A study of Homo sapiens with 4 samples.

How the data were processed

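RNA from 4 samples of HEK293T cells was sequenced, 2 transfected with a scrambled siRNA and 2 with siRNAs against LOC284454. Per the labels' protocols, total RNA was treated with DNase and the libraries were read on an Illumina HiSeq instrument; strandedness is not given in the sources used here. The submitters' processing notes name FastQC, TopHat and Cufflinks 2.2.1 and the build hg19, without parameters. Per the file headers, the authors' per-sample values are Cufflinks FPKM per gene with lower and upper bounds and a status, on 63783 rows for 63652 Ensembl gene identifiers. The FPKM sums over rows were 639090 and 586445 in control replicates 1 and 2 and 604687 and 577328 in siRNA replicates 1 and 2, so the values were not rescaled to one total. FPKM keep no read counts, so the depth per sample is unknown and no counting interval is given; few samples and the Cufflinks estimate limit the precision. The authors' deposited comparison table gives FPKM per group, a log2 fold change, a p-value and q-value and a test statistic, which is a score, for the genes the authors kept by a rule not stated; it was described but not retested.

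Values of the 123 identifiers on more than 1 row were summed. The 16 identifiers with a status other than OK in any sample and the 9740 of short RNA types were left out, since FPKM over a row shorter than a fragment is unstable. Genes with a mean of at least 1 FPKM were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided, Benjamini-Hochberg over all genes tested, adjusted p under 0.05). No block for the replicate number was used. Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01, with at least 5 measured members, and again with an estimated correlation and with fry. A list of genes within 500 kb was made from the files' positions. Members were also adjusted over each list alone. LOC284454 was found in the files by its Ensembl identifier, whose symbol in the files is MIR24-2 and in the gene name table MIR23AHG, and was compared by an exact permutation test over the 6 regroupings.

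Named genes followed a rule written before the data were examined: LOC284454, DDX5 and DDX17; up to 12 genes per direction with the largest change among those that passed with groups that did not overlap, filled with the smallest p; up to 4 members of lists that passed or held a gene that passed and 2 of other lists, by p; and the 5 largest changes per direction in the authors' table with at least 1 FPKM in both groups. Pseudogenes and unnamed clones were skipped for the ranked parts. A few further list members with their values were named after these were seen, and 1 gene of the rule is not reported here.

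The test was checked on simulated data for the 13878 genes, with 200 changed genes. It recovered 58.2% of 67 changes of log2 0.5, 95.5% of 67 changes of log2 1 and all 66 changes of log2 2, called 11 unchanged genes in that simulation, and called 0 genes in a simulation with no change. The simulated noise was independent between genes and drawn from limma's own fitted variances. With 200 planted changes the adjusted threshold is also easier to reach than with few, so recovery in the data may be lower. The alternatives tried were other pseudocounts, no expression minimum or one of 5 FPKM, quantile, median-ratio and TPM scaling, eBayes without a trend or robust, a replicate block, short RNAs kept, all statuses kept and each sample left out; there the lone sample of a group is assumed to vary like the others. A GC content and transcript length correction (loess, span 0.3) was added after the data were seen and used GENCODE 29 by gene identifier, which covered 96.7% of genes tested; no coordinates of that release were used. Seed sequences were searched in 3' UTRs of at least 50 bases from GENCODE 29 for 11024 protein-coding genes, after regression of the fold change on UTR length, GC content and expression. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Coordinates are those of the files, in hg19.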

Results

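Gene expression was measured by RNA sequencing in HEK293T, a human embryonic kidney line that carries the SV40 large T antigen, a viral protein that binds p53. The 4 samples fell into 2 groups of 2: cells transfected with a scrambled siRNA, used as the control, and cells transfected with a pool of siRNAs against the long non-coding RNA LOC284454. The question was how silencing of this RNA, which the study associates with the RNA helicase p68 (DDX5), affects the expression of other genes. The deposited values were FPKM, fragment counts scaled by the authors to transcript length and library size, and the sequencing depth behind them is unknown. A value of at least 1 FPKM was listed for 14035 and 13948 rows in control replicates 1 and 2 and for 14024 and 14042 rows in siRNA replicates 1 and 2. Across the 13878 genes tested, log2(FPKM + 1) correlated between replicates with r = 0.994 in the control group and r = 0.996 in the siRNA group, against 0.992 to 0.995 between groups. Control replicate 2 correlated more with siRNA replicate 2 (r = 0.9946) than with control replicate 1 (r = 0.9937), so this measure did not separate the groups. These are correlations across genes, which are not independent replicates. Short RNAs took 12.6% of all FPKM in control replicate 1, against 4.45% in control replicate 2 and 5.21% and 3.53% in siRNA replicates 1 and 2. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

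The silenced RNA itself was listed at a lower level in both siRNA samples, at 42.5% of the control mean. LOC284454 is the host transcript of the miR-23a, miR-27a and miR-24-2 cluster and is listed in the files as MIR24-2 (ENSG00000267519, hg19 chromosome 19, 13945330 to 13947173). Its level was 0.554 ± 0.164 FPKM in control samples and 0.235 ± 0.0125 FPKM in siRNA samples (SD, n = 2 each; two-sided exact permutation p = 0.333, the smallest that 2 against 2 samples allow). The samples read 0.670 and 0.438 FPKM in the controls and 0.244 and 0.226 FPKM after siRNA. LOC284454 lay under the expression minimum of 1 FPKM and was not tested with limma. In siRNA replicate 2 the listed value lay above its own deposited upper bound of 0.0993 FPKM. The deposited bounds of both controls started at 0 and ended at 1.59 and 1.49 FPKM, so this row gives only a weak check of the labels. DDX5 stood at 18.7 ± 1.75 FPKM in control and 19.4 ± 0.305 FPKM in siRNA samples, and its paralog DDX17 at 291 ± 3.44 and 307 ± 1.11 FPKM (SD, n = 2 each). Neither passed the test (limma adjusted p = 0.803 and 0.452), and the direction for DDX5 turned without control replicate 2, to a log2 fold change of -0.035.

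**Figure D1:**
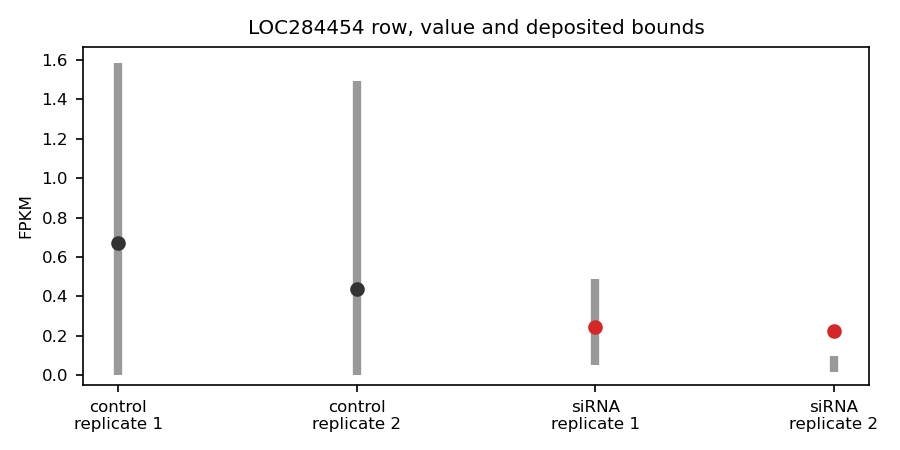
FPKM of the LOC284454 row in each of the 4 samples (points), with the deposited lower and upper bounds as grey bars. The siRNA replicate 2 value of 0.226 FPKM lies above its bar, which ends at 0.0993 FPKM.

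Between LOC284454 siRNA and control samples 9 of the 13878 genes tested passed limma's test at an adjusted p under 0.05, with 6 higher and 3 lower. IFI6, an interferon-induced mitochondrial protein, rose from 21.3 ± 0.124 to 53.8 ± 4.99 FPKM, and ACTA2, smooth muscle actin, rose from 7.25 ± 0.167 to 11.9 ± 0.201 FPKM. PPP1CC, the gamma catalytic subunit of protein phosphatase 1, fell from 121 ± 1.06 to 62.5 ± 2.33 FPKM, and LIPA, the lysosomal acid lipase, fell from 33.8 ± 0.011 to 18.2 ± 0.420 FPKM (SD, n = 2 each). These 4 were the protein-coding genes among the 9. On the log2(FPKM + 1) scale, which understates the change of low genes, IFI6 changed by 1.29 (SE 0.066, adjusted p = 0.000761), ACTA2 by 0.65 (SE 0.064, adjusted p = 0.0368), PPP1CC by -0.95 (SE 0.042, adjusted p = 0.000368) and LIPA by -0.86 (SE 0.048, adjusted p = 0.00107). IFI6 (ENSG00000126709) lies on hg19 chromosome 1 at 27992572 to 27998729, PPP1CC (ENSG00000186298) on chromosome 12 at 111157485 to 111180744, ACTA2 (ENSG00000107796) on chromosome 10 at 90694831 to 90751147 and LIPA (ENSG00000107798) on chromosome 10 at 90973326 to 91174314. The ACTA2 row overlaps those of FAS, STAMBPL1 and ACTA2-AS1, and the LIPA row spans IFIT1, IFIT2 and IFIT3. Reads of overlapping genes can be misassigned where the strand is not known, and the labels do not state it. The values of ACTA2 and LIPA are uncertain to that extent, as are those of FAS and IFIT1 given below.

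The other 5 genes that passed switched between about 0 and a measurable level, and are uncertain. The pseudogenes UBE2Q2P6 (chromosome 15, 82664459 to 82748784) and RPL9P8 (chromosome 15, 83041000 to 83125316) were listed at 0 in both controls and at 0.302 ± 0.133 FPKM, respectively, and at 19.4 ± 2.22 and 22.3 ± 5.20 FPKM after siRNA. RNU6ATAC35P was listed at 0.233 ± 0.0902 and 8.62 ± 1.30 FPKM, and SNORA71B at 0 in both controls and 5.32 ± 0.591 FPKM after siRNA. Both symbols name short RNAs, over rows of 428 and 137 bases that the files type as lincRNA. The pseudogene AC007000.11, a row of 135 bases, was listed at 2.48 ± 0.142 FPKM in controls and at 0 in both siRNA samples (SD, n = 2 each). The 3 pseudogenes stand outside the rule for named genes and were named after their values were seen.

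Other genes with small p and groups that did not overlap lay below the threshold. On the higher side in siRNA samples, RPS27L, a p53-regulated ribosomal protein paralog, read 69.7 ± 0.899 against 53.7 ± 0.0882 FPKM in controls (adjusted p = 0.0546). HMOX1, heme oxygenase 1, read 45.4 ± 1.62 against 34.5 ± 1.23 FPKM (adjusted p = 0.0826). PLEKHG4 read 15.2 ± 0.181 against 11.03 ± 0.451 FPKM (adjusted p = 0.118) and the antisense transcript DNAJC27-AS1 2.37 ± 0.388 against 0.831 ± 0.0519 FPKM (adjusted p = 0.134). On the lower side, PEX19, a peroxisome assembly factor, read 25.7 ± 0.0848 against 34.6 ± 0.723 FPKM (adjusted p = 0.0548). PLAT, tissue plasminogen activator, read 18.8 ± 0.0504 against 25.6 ± 0.864 FPKM, and ANXA5, a phospholipid-binding annexin, 121 ± 2.65 against 155 ± 5.75 FPKM (SD, n = 2 each; limma adjusted p = 0.0753 for both). COMMD3-BMI1, RAB8A, ATXN7L3B, ZC4H2 and CAND1 also read lower, with log2 differences of -0.54, -0.31, -0.30, -0.47 and -0.31 and adjusted p of 0.0753 to 0.139. In all, 1664 genes had an unadjusted p under 0.05, 708 of them higher and 956 lower, and the groups did not overlap for 43.8% of genes, against 33.3% by chance. The number of genes that passed was 21 without control replicate 1, 46 without control replicate 2 and 0 of 30590 without an expression minimum, where 2563 genes had an unadjusted p under 0.05. ACTA2 no longer passed without control replicate 1 (adjusted p = 0.0576), siRNA replicate 1 (adjusted p = 0.388) or siRNA replicate 2 (adjusted p = 0.365), with log2 fold changes of 0.62 to 0.66. It also missed the threshold without an expression minimum (adjusted p = 0.449), without limma's trend (adjusted p = 0.149) and after the GC and length correction (log2 fold change 0.64, SE 0.058, adjusted p = 0.0521), and over its 17 alternatives the adjusted p ran from 0.00409 to 0.449.

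**Figure D2:**
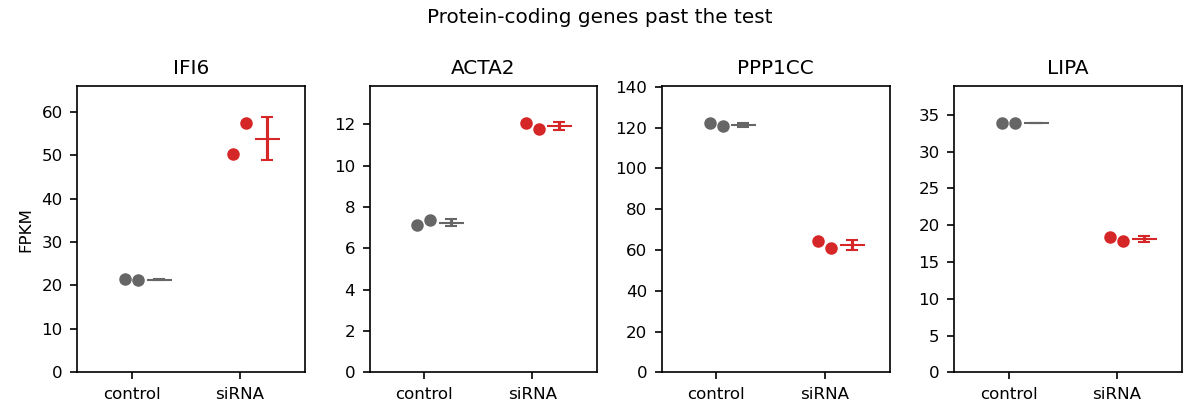
FPKM of IFI6, ACTA2, PPP1CC and LIPA in control (grey) and LOC284454 siRNA (red) samples, each axis starting at 0; points are the 2 samples and bars the mean ± SD. IFI6 reads 21.3 FPKM on average in controls and 53.8 FPKM after siRNA, and PPP1CC 121 and 62.5 FPKM.

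Genes induced by interferon rose as a group in camera's test, which compares a list with all other genes, with a preset correlation between genes (adjusted p = 2.26e-09 over 25 lists). The call was lost with an estimated correlation (adjusted p = 0.523), and fry, which asks whether the list's genes move one way, gave an adjusted p = 0.0156. The correlation estimated within this list was -0.017, below the preset 0.01, so the loss does not come from a higher correlation between its genes. The estimating version has little power with 2 samples per group, and none of the 25 lists passed it. Of 17 measured members, 14 were higher in siRNA samples, with a mean log2 fold change of 0.34 (SD over members 0.38). IFI6 alone passed over all genes tested, and 10 were higher and 1 lower when adjusted over the list alone. IRF9, a component of the interferon-stimulated transcription complex, read 11.6 ± 0.361 against 6.31 ± 0.734 FPKM in controls (limma adjusted p = 0.0548), and the ubiquitin-like modifier ISG15 13.2 ± 2.35 against 7.54 ± 1.13 FPKM. The antiviral membrane protein IFITM1 read 8.24 ± 0.311 against 4.83 ± 0.573 FPKM and IFIT1 4.36 ± 0.0916 against 2.49 ± 0.197 FPKM (SD, n = 2 each). IRF9 passed over all genes tested under 7 of its 17 alternatives (adjusted p = 0.00207 to 0.503 over all 17), IFITM1 under 3, ISG15 under 2 and IFIT1 under 1. Among the members on the lower side, IFIT5 read 6.57 ± 0.140 against 7.72 ± 0.128 FPKM, and IFITM3 and ISG20 had log2 differences of -0.068 and -0.044.

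Targets of p53 rose as a group in camera's test with the preset correlation (adjusted p = 1.09e-10). The call was lost with an estimated correlation (adjusted p = 0.916) and with fry (adjusted p = 0.199). Within this list the estimated correlation was 0.24, against the preset 0.01. Of 24 measured members 22 were higher in siRNA samples, with a mean log2 fold change of 0.19 (SD over members 0.15). None passed over all genes tested, and 13 were higher and 1 lower when adjusted over the list alone. The cell cycle inhibitor CDKN1A read 69.7 ± 1.43 against 54.7 ± 3.28 FPKM in controls, and the death receptor FAS 8.41 ± 0.0324 against 5.94 ± 0.0527 FPKM. Ferredoxin reductase FDXR read 23.04 ± 0.173 against 17.6 ± 1.47 FPKM and the antiproliferative gene BTG2 22.9 ± 0.178 against 17.7 ± 0.533 FPKM. MDM2, the ubiquitin ligase for p53, read 67.0 ± 3.06 against 52.5 ± 6.97 FPKM (SD, n = 2 each). On the lower side were GADD45A, at 69.8 ± 4.57 against 78.1 ± 0.439 FPKM, and GDF15, at 3.82 ± 0.241 against 4.11 ± 0.333 FPKM.

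Hypoxia and glycolysis genes fell as a group in camera's test with the preset correlation (adjusted p = 6.29e-10), a call that was lost with an estimated correlation (adjusted p = 0.916) and with fry (adjusted p = 0.401). Within this list the estimated correlation was 0.83, against the preset 0.01. Of 24 measured members 23 were lower in siRNA samples, with a mean log2 fold change of -0.27 (SD over members 0.18). None passed over all genes tested, and 17 were lower and 0 higher when adjusted over the list alone. The glucose transporter SLC2A3 read 4.10 ± 0.227 against 7.48 ± 0.743 FPKM in controls, and the mitophagy receptor BNIP3L 17.8 ± 0.0765 against 23.8 ± 1.20 FPKM. The pyruvate dehydrogenase kinase PDK1 read 8.53 ± 1.10 against 12.5 ± 1.09 FPKM and phosphofructokinase PFKP 40.0 ± 1.53 against 49.2 ± 1.84 FPKM. Lactate dehydrogenase LDHA read 596 ± 3.34 against 746 ± 100.2 FPKM (SD, n = 2 each). The controls differed from each other in this group: the mean log2 fold change was -0.17 without control replicate 1, the library with the high share of short RNAs, and -0.37 without control replicate 2.

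Messenger RNAs encoded in the mitochondrial genome rose as a group in camera's test with the preset correlation (adjusted p = 6.80e-06), and not with an estimated correlation (adjusted p = 0.916) or with fry (adjusted p = 0.420). Within this list the estimated correlation was 0.76, against the preset 0.01. All 13 were higher in siRNA samples, with a mean log2 fold change of 0.18 (SD over members 0.084), or 0.095 without control replicate 1. None passed over all genes tested and 1 did when adjusted over the list alone: MT-ND3, a complex I subunit, read 3738 ± 195 against 3038 ± 243 FPKM in controls. MT-CYB read 2789 ± 40.7 against 2306 ± 328 FPKM and MT-CO3 6346 ± 299.9 against 5413 ± 522 FPKM (SD, n = 2 each). In control replicate 1 mitochondrial mRNAs summed to 45366 FPKM, against 51130 FPKM in control replicate 2 and 55238 and 53746 FPKM in siRNA replicates 1 and 2. Nuclear-encoded oxidative phosphorylation genes did not pass (mean log2 fold change 0.011, camera adjusted p = 0.584).

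**Figure D3:**
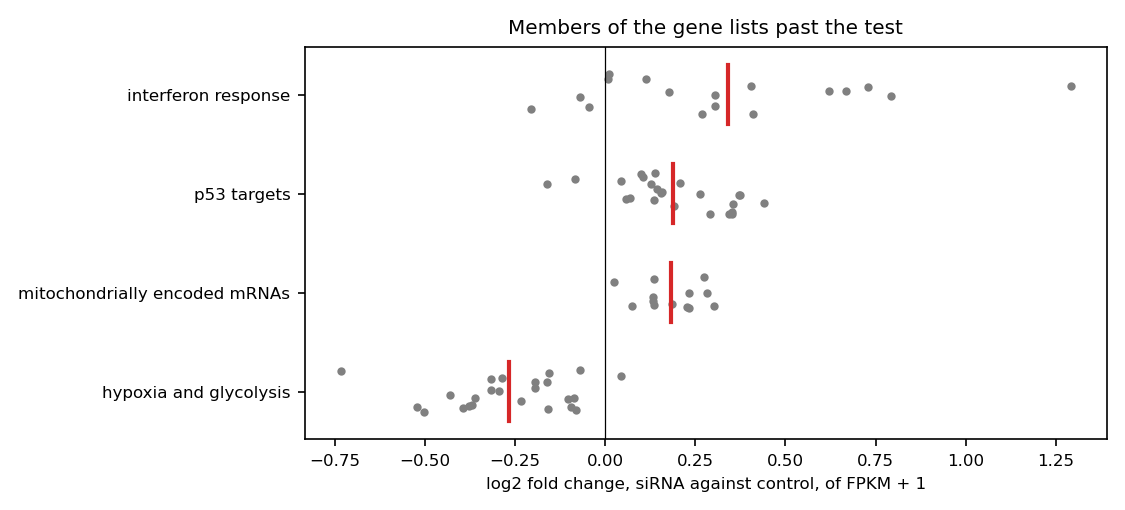
Log2 fold change of FPKM + 1 between LOC284454 siRNA and control samples for each measured member (grey points) of the 4 lists past camera's test with the preset correlation, with the list mean in red. The means are 0.34 for interferon response, 0.19 for p53 targets, 0.18 for mitochondrially encoded mRNAs and -0.27 for hypoxia and glycolysis.

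The remaining 21 lists did not pass in the main comparison. Of these, 4 passed camera's test with the preset correlation under some alternatives: immediate early genes under 6, ribosomal proteins under 4, Wnt pathway genes under 3 and focal adhesion under 1. With an estimated correlation none of the 4 passed (adjusted p = 0.916 to 0.919). Immediate early genes had a mean log2 fold change of -0.13 (camera adjusted p = 0.074), with 6 of 20 members lower and 2 higher when adjusted over the list alone. EGR1, a serum-response transcription factor, read 7.43 ± 0.798 against 11.3 ± 0.439 FPKM in controls and the orphan receptor NR4A1 9.30 ± 1.34 against 14.4 ± 0.262 FPKM, while BTG2 was on the higher side. In the stress-response list (mean -0.049, adjusted p = 0.463), the mTOR inhibitor DDIT4 read 81.3 ± 4.63 against 117 ± 20.7 FPKM and ATF3 90.9 ± 4.95 against 109.8 ± 7.16 FPKM (SD, n = 2 each). Among lists on adhesion and matrix, the mean was -0.043 for cell-cell adhesion (adjusted p = 0.35), and -0.057 for focal adhesion and integrins (adjusted p = 0.187). It was -0.030 for extracellular matrix and proteases (adjusted p = 0.837) and -0.0066 for epithelial-mesenchymal transition (adjusted p = 0.837). SPARC, a matrix glycoprotein, read 21.8 ± 0.347 against 26.3 ± 0.465 FPKM, VCL, vinculin, 26.98 ± 1.25 against 30.0 ± 0.755 FPKM, and ID3 69.9 ± 1.69 against 61.1 ± 1.00 FPKM. Wnt pathway genes had a mean of -0.067 (adjusted p = 0.187), with CCND1, cyclin D1, at 9.92 ± 0.047 against 12.7 ± 1.30 FPKM. For proliferation genes the mean was 0.042 for G1/S and DNA replication (adjusted p = 0.0898) and 0.019 for G2/M and mitosis (adjusted p = 0.357). E2F1 read 34.7 ± 0.610 against 30.0 ± 1.57 FPKM and UNG, uracil-DNA glycosylase, 69.7 ± 0.637 against 60.4 ± 0.199 FPKM (SD, n = 2 each).

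Reported targets of miR-23a, miR-27a and miR-24 had a mean log2 fold change of -0.021 over 27 measured members (adjusted p = 0.837), and the list of the microprocessor and p68 partners 0.0048 (adjusted p = 0.613). In the latter 9 of 14 measured members were higher. AGO2 read 6.91 ± 0.152 against 8.70 ± 0.913 FPKM in controls and SRA1 38.4 ± 0.659 against 34.9 ± 1.90 FPKM (SD, n = 2 each; limma adjusted p = 0.298 and 0.394). The 17 measured genes within 500 kb of LOC284454 had a mean of -0.013, a median of 0.011 and an upward direction in camera (adjusted p = 0.837). The mean was 0.033 for ribosomal proteins (adjusted p = 0.074), 0.044 for NF-kB and inflammatory genes (adjusted p = 0.35, with a median of -0.0014) and -0.011 for ribosome biogenesis and MYC targets (adjusted p = 0.837, with camera's direction upward). It was -0.020 for heat shock (adjusted p = 0.830), -0.017 for cholesterol and fatty acid synthesis (adjusted p = 0.837) and -0.033 for histones (adjusted p = 0.837). For the last lists it was -0.0079 for splicing factors (adjusted p = 0.963) and -0.015 for apoptosis regulators (adjusted p = 0.862). Markers of fibroblasts, blood cells, breast or cervical epithelial lines and hepatocytes were mostly under 1 FPKM in every sample, for 8 of 10, 9 of 10, 8 of 10 and 8 of 8 genes. The highest sample values were 6.60 FPKM for COL1A1, 4.72 FPKM for GATA3 and 0.333 FPKM for APOA2 in the fibroblast, epithelial and hepatocyte lists.

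The authors' deposited table of filtered genes held 39 genes higher and 56 lower after siRNA, all with a p of at most 0.0096. None was marked significant there, and the smallest q in the authors' deposited table was 0.0567, shared by 12 genes. The ranking took genes with at least 1 FPKM in both groups and skipped pseudogenes and unnamed clones. Among these genes, the authors' deposited table gave the highest log2 fold changes to IFI6 (1.33), RMRP, the RNA component of an endoribonuclease (0.90), DDX60 (0.81), ISG15 (0.79) and OAS3 (0.77). The RMRP row is short (chromosome 9, 35657748 to 35658015), so its FPKM may be unstable. The lowest in the authors' deposited table went to CD44, a hyaluronan receptor (-1.19), PPP1CC (-0.92), LIPA (-0.88), PIANP (-0.88) and the short RNA RN7SL3 (-0.87). Of the fixed lists, interferon response held 6 of the genes higher in the authors' deposited table (DDX58, OAS3, IFI6, IFI44L, IFITM1 and ISG15), and hypoxia and glycolysis 5 of those lower (SLC2A3, P4HA1, PDK1, HK2 and BNIP3). In the per-sample values all 95 genes had the same direction and 92 had groups that did not overlap. Of the 78 that entered the test, 5 passed limma's test at an adjusted p under 0.05 and 65 had an unadjusted p under 0.05. The table comes from the same libraries, so this is no independent evidence. The largest drop in the authors' deposited table, C1orf132 from 402 to 0.209 FPKM, rests on control replicate 1. The samples read 699 and 0.154 FPKM in the controls and 0.196 and 0.181 FPKM after siRNA, so control replicate 2 lies below both siRNA samples. C1orf132 was named after its values were seen.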

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

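The check of the LOC284454 row against its bounds and the GC and length correction were chosen after the data had been seen. Short RNAs were outside the comparison; when they were kept, 9 passed limma's test, 4 with a value of 0 FPKM in both controls and a higher one in both siRNA samples and 5 the other way. For the 4, the log2 fold changes were 3.16 for a Y_RNA row (9.48 and 6.65 FPKM after siRNA), 2.37 for RNA5SP78 (4.97 and 3.45 FPKM), 2.43 for RNA5SP216 (3.73 and 5.17 FPKM) and 2.58 for RNU6-548P (5.96 and 4.17 FPKM), with adjusted p of 0.00641, 0.0241, 0.0174 and 0.0174. Of the 5, another Y_RNA row read 5.53 and 5.39 FPKM in the controls, RNU2-27P 7.24 and 7.92 FPKM and SNORA34 2.17 and 2.35 FPKM, and these were listed at 0 in both siRNA samples, except 6.94e-43 FPKM for Y_RNA in siRNA replicate 2 (adjusted p = 0.00307, 0.0017 and 0.0331). The others were the mitochondrial transfer RNAs MT-TA and MT-TE (adjusted p = 0.000253 and 9.97e-09). Other mitochondrial transfer RNA rows held 26647 and 15417 FPKM in siRNA replicates 1 and 2. In control replicate 2 MT-TA and MT-TE made up the whole class sum of 25255 FPKM, so these other rows held none there.

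The interferon and p53 lists rose and the hypoxia list fell in camera's test with the preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.523, 0.916 and 0.916), and with fry only interferon response passed (adjusted p = 0.0156, 0.199 and 0.401). The correlations estimated within the lists were -0.017, 0.24 and 0.83, so for interferon response a higher correlation does not account for the loss. None of the 25 lists passed the estimating version, which has little power with 2 samples per group. GC content and transcript length bias is argued against as the whole cause, since after its removal the 3 lists kept at least 97.7% of their mean log2 fold change (highest camera adjusted p = 1.06e-08). Scaling shifted by a few abundant RNAs is argued against likewise, with at least 95.4% kept under quantile and median-ratio scaling (highest adjusted p = 8.12e-09). A single library as the whole source is argued against, since all 3 lists kept their direction whichever library was left out. The lowest share kept was 62.9%, for the hypoxia list without control replicate 1. That list's mean was -0.17 without control replicate 1 and -0.37 without control replicate 2, so its size depended on the control used. With 1 siRNA pool and 1 scrambled siRNA, silencing of LOC284454 and other effects of the pool on interferon, p53 or hypoxia genes stay open as untested explanations.

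Of the 9 genes that passed, 5 were switch-like, with a group mean under 10% of the other's. With reads shared between near-identical copies, a row of the same family or an overlapping row should lose what another gains. This held for 0 of the 4 switch-like rows that had any such row, while RNU6ATAC35P had none and was not searched. The test asked for a single row that moved the opposite way by a set share of the FPKM. As FPKM are scaled to length, reads taken from several rows or from a row of another length could escape it. Reads taken from a copy under another symbol, and estimates that failed at 0, remain possible: UBE2Q2P6 and RPL9P8 may be affected by the first, lying in rows of 84326 and 84317 bases on chromosome 15, and the rows of 135 to 428 bases by the second. No biological explanation was tested.

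The FPKM of LOC284454 lay away from the midpoint of its deposited bounds in both siRNA samples. Among 71854 values with status OK and a lower bound above 0, 71852 equalled that midpoint within a relative 0.0001, and 0 values of any other row departed from it, which argues against a general property of the intervals in these files. Values at the midpoints would be 0.269 and 0.0569 FPKM, or 29.4% of the control mean in place of 42.5%. The LOC284454 value of siRNA replicate 1 was also listed with more significant digits than any other value in the 4 samples. How these values came to differ from their bounds stays open.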

How the results depend on the processing

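The GC and length correction, the midpoint values for LOC284454 and the lists without shared members were chosen after the data had been seen; the other alternatives were planned. The 4 list calls kept their direction under every alternative and camera's threshold under every scaling, filter and left-out sample, and the causes of the shifts below were not tested unless stated. The number of genes that passed limma's test, 9 in the main comparison, was 0 without an expression minimum (30590 tested; 2563 at an unadjusted p under 0.05), 17 with at least 5 FPKM (9430 tested; 6 of the 9 kept), 40 after TPM scaling (15295 tested; 27 higher, 13 lower), 18 with short RNAs kept, and 11 to 46 with a sample left out, where 21 passed without control replicate 1 and, without control replicate 2, 18 were higher and 28 lower, against 6 and 3. With a replicate block 19 passed, all 9 among them. The correlation of same-numbered deviations was 0.078. This cannot tell whether samples of the same number shared a culture or day, which the labels do not state. The number of lists was 8 without a minimum, 0 with an estimated correlation and 1 with fry; with the estimated correlation the means of 0.19 for p53 targets, 0.34 for interferon response, -0.27 for hypoxia and glycolysis and 0.18 for mitochondrially encoded mRNAs no longer passed (adjusted p = 0.916, 0.523, 0.916 and 0.916), and with fry all but interferon response no longer passed. The LOC284454 difference of -0.32 FPKM was -0.50 after TPM scaling, which multiplies all values, and -0.20 to -0.43 with a sample left out. The mean correlation between replicates, 0.995, was 0.990 at a pseudocount of 0.1 and 0.997 without a minimum. All 95 directions of the authors' genes held, except 1 gene without control replicate 1 or without siRNA replicate 1. Without depth, low genes cannot be given a detection limit.

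Some lists that did not pass had means near 0 that turned sign. The median log2 fold change over all genes tested was -0.012 in the main comparison. It was 0.036 after TPM scaling, -0.0026 after quantile scaling, -0.00027 after median-ratio scaling and -0.00077 after the GC and length correction. Under these alternatives a list near 0 could therefore turn sign with the shift of all genes. Without a minimum the mean was 0.0070 for epithelial-mesenchymal transition and 0.0063 for genes within 500 kb; with at least 5 FPKM it was 0.013 and 0.016 for these and 0.0083 for histones. Quantile scaling gave 0.0027 for epithelial-mesenchymal transition and 0.00033 for splicing factors, and median-ratio scaling 0.0045 and 0.0047 for these and 0.0011 for ribosome biogenesis. TPM scaling gave 0.0072 for extracellular matrix, 0.053 for epithelial-mesenchymal transition, 0.026 for miRNA targets, 0.030 for heat shock, 0.033 for cholesterol synthesis, 0.039 for ribosome biogenesis, 0.024 for histones, 0.043 for splicing factors, 0.032 for apoptosis and 0.031 for genes within 500 kb. The GC and length correction gave 0.0053 for epithelial-mesenchymal transition, 0.0084 for ribosome biogenesis and 0.0085 for splicing factors. With a sample left out the means ran from -0.014 to 0.0073 for epithelial-mesenchymal transition, -0.027 to 0.0052 for genes within 500 kb, -0.021 to 0.043 for oxidative phosphorylation, -0.0025 to 0.068 for ribosomal proteins, -0.0054 to 0.015 for the microprocessor list and -0.038 to 0.0073 for apoptosis, and the log2 fold changes from -0.035 to 0.15 for DDX5 and from -0.079 to 0.13 for GATA3.

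Calls were also gained. Immediate early genes, with a negative mean under each alternative, passed without a minimum (adjusted p = 0.00339), with median-ratio (0.0479) or TPM scaling (0.0108), without control replicate 2 (0.0209) or siRNA replicate 1 (0.0401) and after the GC and length correction (0.033). Ribosomal proteins passed without a minimum, with at least 5 FPKM, with median-ratio scaling and without siRNA replicate 2 (adjusted p = 0.00126 to 0.0451), Wnt genes under the same but for median-ratio scaling (0.0242 to 0.0472), and focal adhesion without a minimum (0.0487). Over all alternatives the highest adjusted p was 0.916, 0.943, 0.917 and 0.958 for these lists. Of the named genes, IRF9 passed under 7 alternatives, RPS27L under 5, SLC2A3 under 4, HMOX1, IFITM1 and PEX19 under 3, ANXA5, DDIT4, RMRP and ISG15 under 2, and DNAJC27-AS1, IFIT1, PLAT, COMMD3-BMI1 and LDHA under 1.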

Other observations

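Some values stood outside the comparisons above and were chosen after they were seen. The mitochondrial transfer RNA MT-TA was listed at 25063 and 13024 FPKM in control replicates 1 and 2, and MT-TE at 11848 and 12231 FPKM, and both were listed at 0 in both siRNA samples. All mitochondrial transfer RNA rows summed to 73169 and 25255 FPKM in control replicates 1 and 2. They summed to 26647 and 15417 FPKM in siRNA replicates 1 and 2, all of it in other rows of this class, so the class as a whole was not lost. In control replicate 2 MT-TA and MT-TE made up the whole sum, so the other rows held none there. In control replicate 1 other rows held part of the sum. ACTA2 and LIPA, which moved in opposite directions, both lie on chromosome 10, where the ACTA2 row ends at 90751147 and the LIPA row starts at 90973326, with most of the FAS row between them.

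Both hypotheses below were written before their results were seen. LOC284454 is the host transcript of 3 miRNAs, so silencing it could lower them and raise genes with their seed matches. Among heptamers of the same bases, the seed match of miR-24-3p ranked at percentile 62.2 for higher fold changes, that of miR-27a-3p at 36.7 and that of miR-23a-3p at 0.957, so none was in the highest 5% that the hypothesis needs. Genes with the miR-23a-3p match AATGTGA had a mean log2 fold change of -0.038 over 2089 genes, against -0.0093 without it, but after regression on UTR length, GC content and expression the difference was -0.0058 (z = -2.08), so most of that gap is not attributed to the match. The regressed differences were -0.00016 for miR-27a-3p and 0.0022 for miR-24-3p.

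Genes could also fall because an siRNA of the pool acts through its seed on 3' UTRs; the siRNA sequences were not used here. Of 15530 heptamers, the one most associated with lower fold changes, CTGTGTG, had z = -4.70 over 2442 genes, and the one most associated with higher fold changes had z = 3.49. The next lowest was TGTGTGT, a TG repeat that overlaps CTGTGTG in sequence, with z = -4.07 over 2925 genes. In 100 permutations of the fold changes over genes the highest |z| was 5.14, and 2 of them reached a |z| as large as that of CTGTGTG. The prediction for an off-target seed asked for a |z| above all permutations and was not met, but so few reached the observed value that it is not excluded either, a reading added after the result was seen.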
